A study of Mus musculus with 4 samples.

How the data were processed

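The study measured RNA of single nuclei from micropunched mouse PVN tissue, isolated on a sucrose gradient, with the 10x Genomics droplet assay for the 3' ends of transcripts. The deposited matrices hold raw UMI counts per gene and barcode, 1 matrix for each of 2 ZT8 and 2 ZT20 libraries. Per the file headers the counts come from Cell Ranger 7.0.0, and the authors' notes name Cell Ranger, STAR 2.6 and the mouse genome build mm10. How reads in introns were counted and how barcodes were called is not stated. No normalization was applied before deposit. Genes were matched by Ensembl identifier to GENCODE release M21 for mm10, and coordinates are given on that build.

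Nuclei with at least 500 genes and at most 5% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet as implemented in scanpy 1.11.5 under Python 3.11.15. Its automatic threshold marked 2, 707, 4 and 1 nuclei in the ZT8 and ZT20 libraries, so the highest scores were removed instead, at 0.8% of nuclei per 1000 nuclei in the library (326 to 702 nuclei). Counts were scaled per nucleus and log-transformed, and 3000 variable genes were chosen within libraries, leaving out mitochondrial, clock, immediate early, heat shock and glucocorticoid genes. Then 40 principal components, 20 nearest neighbours with shared-neighbour weights and Leiden clustering at resolution 1 (leidenalg 0.10.2, seed 0) gave 34 clusters, and the same steps within neurons gave 39. Libraries were not aligned to each other, since that would need an assumption about what the times share.

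Clusters were named from markers of 23 classes written before the data were examined. A cluster took the name of its best class when at least 3 markers were detected in at least 10% of its nuclei, its scaled marker score was at least 0.7, its 10 leading genes held no more markers of another class than of its own, its median doublet score was under 0.08, and it did not combine a median UMI count under 0.333 of its library's median with a lack of own markers among the leading genes. Neuron clusters needed a median of at least 2000 UMIs and a median doublet score under 0.1. GABAergic-like clusters needed a score of at least 0.6, and regional names a score of 0.7, or 0.5 with 2 markers among the leading genes. For a transmitter name, the leading genes against clusters of the other transmitter had to hold no fewer own markers than markers of another neuron class. Thalamic and PVN markers did not count against glutamatergic names. The score thresholds were set after the clusters had been seen. Scoring by medians, leading genes without a pseudocount of 100 CPM, and centring each library before the principal components had been tried and were dropped. 22 clusters were named and 12 were not. Nuclei kept out of the named classes were 24.7, 25.4, 37.7 and 46.03% of the 4 libraries (ZT8 then ZT20) for few UMIs, 5.90, 6.54, 3.24 and 3.51% for doublet scores and 1.83, 1.40, 3.25 and 2.93% for low marker scores; they count in all nuclei pooled.

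The library is the replicate: UMI counts were summed per library and class, and ZT20 was compared with ZT8 (2 against 2) with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM normalization, robust quasi-likelihood F tests, two-sided, and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Equal replicate numbers were not read as pairs, since the labels give no shared day or litter. Classes with at least 50 nuclei in every library were tested, and so was each neuron cluster of that size by number, with or without a regional name. Differences between classes used a model with library, class and the class by time term. CPM are counts scaled so that every library sums to the same total. Shares were compared by an exact two-sided permutation test. With 2 libraries per time, other splits of the libraries and single outlying libraries were not tested.

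The tests, the rule for the genes named and 18 gene lists were fixed before the data were examined: core clock with its PER, REV-ERB and DBP arm and its BMAL1 arm, clock outputs, glucocorticoid response, immediate early, heat shock, neuropeptide, feeding and stress receptor, ion channel, GABA and glutamate transmission, astrocyte function, myelin, cholesterol synthesis, unfolded protein response, mitochondrially encoded, ribosomal protein and nuclear long noncoding genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and at an estimated one, and with fry, on log-CPM with a prior count of 2; fry tests whether a list moves one way and does not compare it with other genes. Named genes are all core clock genes tested, up to 8 genes per direction with the smallest p among called genes whose libraries do not overlap (3 in the smaller classes, with 9 clock genes), and up to 4 members per list with the smallest p. Genes with only a Gm or Rik name were passed over, 2 in all. Some genes that this rule selects are not printed in the text. Peptide genes in glia and the neuropeptide genes beyond 4 in neurons were added after their values had been seen.

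Alternatives fixed before the data were examined were RLE size factors, the DESeq2 1.42.0 Wald test, no low-count filter, a replicate term, sums thinned to the smallest library, doublets kept, at least 1000 genes with at most 1% mitochondrial UMIs, Leiden resolution 2, and leaving out each library in turn; with 1 library left at a time, that library is assumed to vary like the others. Chosen after seeing the data were drawing the same number of nuclei of each neuron cluster from every library, subtracting the profile of a library's unnamed nuclei under 2000 UMIs scaled to genes the class should lack, using nuclei of named classes only, and thalamic-like neurons as a class. The background so estimated was 6.43 to 8.83% of UMIs in neuron-like, 17.6 to 21.1% in astrocyte-like, 24.4 to 25.9% in oligodendrocyte-like and 28.3 to 31.6% in microglia-like nuclei. It is scaled on neuropeptide genes in glia and therefore does not test those.

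The tests were checked on simulated counts with 200 changed genes. A 2-fold change was called in the right direction for 86% of genes in all nuclei, 90% in neurons, 88% in astrocytes, 70.8% in oligodendrocytes, 63.04% in OPCs, 46.9% in microglia, 91.8% in GABAergic and 89.8% in glutamatergic neurons, and edgeR called 0 genes when none was changed. The test of class differences, simulated for neurons and astrocytes only, found 48% of 2-fold differences with 1 false call. A core clock list raised 1.5-fold gave a camera adjusted p = 8.6e-17, and 0 of 15 lists without shared genes passed. Both checks hold at their simulated spread only and do not test correlated genes. Sums per class ran from 35048544 UMIs in neurons to 285189 in microglia, which sets what can be seen in each. Intervals of shares cover counting error only.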

Results

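Nuclei of the mouse paraventricular nucleus of the hypothalamus (PVN), a centre of neuroendocrine, stress and feeding control, were profiled by droplet single-nucleus RNA sequencing at 2 zeitgeber times (ZT, counted from lights on). Per the labels, each library pooled PVN tissue of 5 male C57BL/6 mice aged 10 weeks, and 2 libraries were made at ZT8 (day) and 2 at ZT20 (night). The series sets day against night, so each comparison asks which nuclei or transcripts differed between ZT8 and ZT20. The ZT8 libraries held 6453 and 6923 barcodes with 57970649 and 69223344 unique molecular identifiers (UMIs), and the ZT20 libraries 8320 and 9413 barcodes with 63558166 and 61933800 UMIs. After filtering, 6053 and 6513 nuclei at ZT8 and 7747 and 8667 at ZT20 remained, with medians of 4366 and 5148 UMIs against 3437 and 2063, and of 2359 and 2610 genes against 1995 and 1410. Neuron-like nuclei had medians of 13084 and 14618 UMIs at ZT8 and 12484 and 12068 at ZT20. Replicate libraries of 1 time were close to each other: in neuron-like nuclei the chi-square per gene was 1.66 at ZT8 and 1.65 at ZT20, against 28.7 to 33.3 between times. Random divisions of the nuclei of 1 time into parts gave a value as large in 9 (ZT8) and 14 (ZT20) of 100 draws there. The corresponding counts were 30 and 0 in all nuclei, 0 and 1 in astrocyte-like and 4 and 53 in oligodendrocyte-like nuclei. All p-values measure only the spread between these libraries, part of which can be technical, and the labels do not say whether the 2 libraries of a time came from separate mice.

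The PVN and its surroundings hold neuroendocrine and other neurons, astrocytes, oligodendrocytes that make myelin, vascular cells and, along the ventricle, ependymal cells and tanycytes, glia that line the ventricle wall. The makeup of the libraries differed between ZT8 and ZT20: oligodendrocyte-like and thalamic-like nuclei took smaller shares at ZT20, and Sim1-positive PVN-like neurons, ventromedial- or arcuate-like neurons and tanycyte-like nuclei larger ones. Class names stand for nuclei whose cluster is like that type by markers fixed beforehand. Neuron-like nuclei were 38.9 ± 0.0462% at ZT8 and 34.3 ± 3.38% at ZT20 of kept nuclei (mean ± SD, n = 2 libraries per time). Astrocyte-like nuclei were 6.50 ± 0.764% at ZT8 and 5.08 ± 0.644% at ZT20. Oligodendrocyte-like nuclei were 14.8 ± 0.0984% at ZT8 and 6.44 ± 1.28% at ZT20. Thalamic-like neurons (markers such as Tcf7l2 and Prkch) went from 21.03 to 9.39%. Neurons like the Sim1-positive neurons of the PVN went from 0.342 to 2.22%, with 20 and 23 nuclei at ZT8 and 198 and 164 at ZT20. They were 0.330% (95% Clopper-Pearson interval 0.202 to 0.510%) of nuclei in ZT8 replicate 1 and 2.56% (95% Clopper-Pearson interval 2.22 to 2.93%) in ZT20 replicate 1. Ventromedial- or arcuate-like neurons, 1 cluster with the markers Pomc and Npy among its leading genes, numbered 2 and 1 nuclei at ZT8 and 145 and 140 at ZT20. Tanycyte-like nuclei, with markers such as Rax and Col23a1, numbered 1 and 1 nuclei at ZT8 and 93 and 93 at ZT20. GABAergic-like neurons were 6.04 ± 0.0314% at ZT8 and 5.69 ± 0.572% at ZT20. Glutamatergic-like neurons were 18.2 ± 0.132% at ZT8 and 14.4 ± 1.87% at ZT20. Neurons without a transmitter name were 14.7 ± 0.209% at ZT8 and 14.2 ± 0.939% at ZT20. Among these, clusters 10, 14, 16, 17, 30 and 33 reached the GABAergic score of 0.6 and held more nuclei at ZT20. Cluster 10 held 48 and 41 nuclei at ZT8 and 138 and 149 at ZT20. Cluster 35, with few UMIs, reached that score and held fewer at ZT20. No direction is therefore read for GABAergic neurons as a whole. Oligodendrocyte precursor-like (OPC-like) nuclei went from 2.20 to 1.83%, microglia-like from 1.97 to 1.497%. Endothelial-like nuclei went from 1.41 to 0.605%, fibroblast-like from 0.645 to 0.298%, mural-like from 0.436 to 0.227% and ependymal-like from 0.198 to 0.185%. For all of these classes except ependymal-like nuclei, GABAergic-like nuclei and neurons without a transmitter name, both ZT20 libraries lay on one side of both ZT8 libraries. Their exact two-sided permutation p = 0.333 is the smallest that 2 against 2 libraries allow. Nuclei in unnamed clusters, mostly with few UMIs, went from 32.9 to 48.3% and lower every other share at ZT20. As a share of the nuclei in named classes alone, neuron-like nuclei went from 57.96 to 66.6%, astrocyte-like from 9.68 to 9.83%, GABAergic-like from 9.003 to 11.02% and glutamatergic-like from 27.1 to 27.9%. OPC-like nuclei then went from 3.28 to 3.54% and ependymal-like from 0.296 to 0.355%, so these classes were not lower at ZT20 on that scale. With at least 1000 genes and at most 1% mitochondrial UMIs per nucleus, the ZT20 minus ZT8 difference turned from -4.54 to 7.91 points for neuron-like, from -1.42 to 0.397 for astrocyte-like and from -0.352 to 9.90 for GABAergic-like nuclei. Clusters were formed and named anew in that setting. GABAergic-like nuclei then numbered 488 and 503 at ZT8 and 939 and 949 at ZT20, against 367 and 392, and 472 and 458, before. That class is therefore not the same set of neurons.

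**Figure D1:**
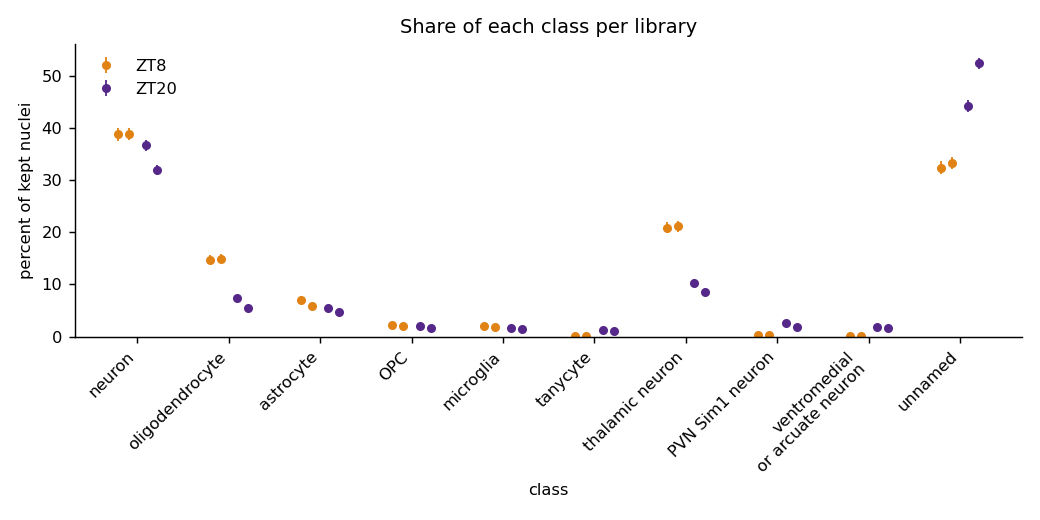
Percent of kept nuclei in each library for 10 classes, with 95% Clopper-Pearson intervals that cover counting error only. Oligodendrocyte-like nuclei lie at about 14.8% in the ZT8 libraries and 6.44% on average in the ZT20 libraries. Punch placement and time of day cannot be told apart here.

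In all nuclei pooled, Slit2, Nnat, Dlk1, Hspa5 and the mitochondrially encoded genes were higher at ZT20, and Acta2, Myh11 and the myelin genes lower. Of the clock genes, Nr1d1, Ciart, Dbp and Per1 were lower and Per2 and Nfil3 higher. Slit2 encodes an axon guidance ligand, Nnat (neuronatin) and Dlk1 are imprinted genes expressed in hypothalamic neurons, Hspa5 encodes the endoplasmic reticulum chaperone BiP, and Acta2 and Myh11 encode contractile proteins of vascular smooth muscle. Slit2 rose from 103 ± 2.61 to 215 ± 0.857 CPM (log2 change 1.02 ± 0.03 SE, edgeR adjusted p = 1.8e-19). Slit2 (ENSMUSG00000031558) lies on the plus strand of chromosome 5 from 47983138 to 48307733. Nnat rose from 113 ± 2.42 to 231 ± 3.92 CPM (log2 change 0.99 ± 0.03 SE, edgeR adjusted p = 2.1e-19). Nnat (ENSMUSG00000067786) lies on the plus strand of chromosome 2 from 157560078 to 157562522. Dlk1 rose from 18.8 ± 1.28 to 59.1 ± 1.26 CPM (log2 change 1.61 ± 0.04 SE, edgeR adjusted p = 5.7e-19). Dlk1 (ENSMUSG00000040856) lies on the plus strand of chromosome 12 from 109452823 to 109463336. Hspa5 rose from 83.8 ± 2.09 to 167 ± 2.00 CPM (log2 change 0.96 ± 0.03 SE, edgeR adjusted p = 1.2e-18). Hspa5 (ENSMUSG00000026864) lies on the plus strand of chromosome 2 from 34771970 to 34777547. Acta2 fell from 25.6 ± 1.07 to 0.794 ± 0.0454 CPM (log2 change -5.04 ± 0.10 SE, edgeR adjusted p = 7.8e-22). Acta2 (ENSMUSG00000035783) lies on the minus strand of chromosome 19 from 34241090 to 34255590. Myh11 fell from 18.4 ± 0.242 to 0.909 ± 0.156 CPM (log2 change -4.37 ± 0.10 SE, edgeR adjusted p = 4.6e-20). Myh11 (ENSMUSG00000018830) lies on the minus strand of chromosome 16 from 14194535 to 14291372. Among the genes with the smallest p were also Dgkb (0.74 ± 0.02), Tafa1 (0.80 ± 0.02), mt-Co3 (0.83 ± 0.02) and mt-Cytb (0.93 ± 0.03) higher, each as log2 change ± SE. Lower were Rnf220 (-0.72 ± 0.02), Prkch (-0.93 ± 0.03), Kcnip4 (-0.65 ± 0.02), Synpo2 (-0.81 ± 0.02), Ptpn3 (-0.77 ± 0.02) and Vav3 (-0.71 ± 0.02), with edgeR adjusted p of 7.9e-19 to 1.1e-17 over these 10 genes. The clock genes Nr1d1 (-0.84 ± 0.05), Ciart (-0.80 ± 0.07), Dbp (-0.62 ± 0.05) and Per1 (-0.42 ± 0.04) were lower. Per2 (0.28 ± 0.05) and Nfil3 (0.40 ± 0.09) were higher (adjusted p 2.6e-12 to 6.3e-04). Arntl (-0.03 ± 0.03) and Cry1 (-0.05 ± 0.05) did not pass. For every gene given as higher or lower, both ZT20 libraries lay on one side of both ZT8 libraries. In total 5103 genes were higher and 4932 lower at ZT20 among 21040 tested. DESeq2 called 6426, and 801 of the edgeR calls exceeded 2-fold. Of the fixed lists, the neuropeptide list had 22 higher and 1 lower of 25, and the myelin list 16 of 16 lower. The mitochondrially encoded list had 13 of 13 higher, the ribosomal protein list 22 of 22 higher and the core clock list 2 higher and 16 lower of 24. Camera with the preset correlation passed 13 of 18 lists, fry 15, and camera with an estimated correlation 0, with 2 lists at an unadjusted p under 0.05. The BMAL1 arm list had a median log2 change of -0.04, a mean of 0.02 and a camera direction of down. These values mix changes within classes with the different makeup of the libraries; in the nuclei of named classes alone 7937 of the 10035 calls remained in the same direction.

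In neuron-like nuclei, most genes of the PER, REV-ERB and DBP arm of the circadian clock were lower at ZT20 than at ZT8, and Per2 was higher. Nr1d1 and Nr1d2 encode the REV-ERB receptors, which repress Arntl, the gene of the clock activator BMAL1. Dbp, Hlf and Tef encode transcription factors driven by CLOCK and BMAL1, Ciart and Bhlhe40 encode repressors of that pair, and the Per and Cry genes encode the repressors of the core loop. Nr1d1 fell from 18.4 ± 0.388 to 10.7 ± 0.277 CPM (log2 change -0.84 ± 0.07 SE, edgeR adjusted p = 2.1e-09). Nr1d1 (ENSMUSG00000020889) lies on the minus strand of chromosome 11 from 98767932 to 98775333. Dbp fell from 23.6 ± 0.438 to 16.5 ± 0.712 CPM (log2 change -0.57 ± 0.06 SE, edgeR adjusted p = 8.4e-08). Dbp (ENSMUSG00000059824) lies on the plus strand of chromosome 7 from 45705088 to 45710203. Ciart fell from 12.4 ± 0.408 to 8.16 ± 0.115 CPM (log2 change -0.65 ± 0.08 SE, edgeR adjusted p = 6.1e-07). Ciart (ENSMUSG00000038550) lies on the minus strand of chromosome 3 from 95878503 to 95882251. Bhlhe40 fell from 20.3 ± 0.438 to 13.5 ± 0.934 CPM (log2 change -0.64 ± 0.06 SE, edgeR adjusted p = 7.1e-08). Bhlhe40 (ENSMUSG00000030103) lies on the plus strand of chromosome 6 from 108660629 to 108666925. Per2 rose from 14.3 ± 0.782 to 20.8 ± 0.955 CPM (log2 change 0.49 ± 0.06 SE, edgeR adjusted p = 2.7e-06). Per2 (ENSMUSG00000055866) lies on the minus strand of chromosome 1 from 91415982 to 91459324. Also lower were Npas2 (-0.55 ± 0.03), Hlf (-0.51 ± 0.03), Rorb (-0.50 ± 0.02), Rora (-0.47 ± 0.02), Cry2 (-0.44 ± 0.03), Per1 (-0.37 ± 0.05), Nr1d2 (-0.26 ± 0.03), Tef (-0.18 ± 0.03), Arntl (-0.14 ± 0.03), Cry1 (-0.14 ± 0.06) and Clock (-0.08 ± 0.02), each as log2 change ± SE. Nfil3 (0.41 ± 0.10) was higher (adjusted p 6.7e-14 to 0.0472). Per3 (-0.05 ± 0.04), Arntl2 (0.09 ± 0.05), Csnk1d (-0.05 ± 0.03) and Csnk1e (0.01 ± 0.04) did not pass. Both ZT20 libraries lay on one side of both ZT8 libraries for each of the genes called lower or higher here. The core clock list had 2 higher and 17 lower of 24, with the same counts adjusted over the list alone (camera adjusted p = 9.1e-05 with the preset correlation, adjusted p = 0.181 with an estimated correlation). The PER, REV-ERB and DBP arm had 1 higher and 10 lower of 12 and a median log2 change of -0.41 (camera adjusted p = 8.1e-05 with the preset correlation, adjusted p = 0.181 with an estimated correlation). The BMAL1 arm had 1 higher and 4 lower of 6, with a median of -0.11, a mean of 0.00 and a camera direction of down (camera adjusted p = 0.414, and adjusted p = 0.627 with an estimated correlation). With the same number of nuclei of each neuron cluster drawn from every library, the log2 change was -0.59 for Nr1d1, -0.40 for Dbp and 0.47 for Per2, and turned to 0.12 for Arntl and 0.01 for Cry1, where Arntl passed as higher and Cry1 did not pass. Npas2, at -0.06, Rorb, at -0.05, Per1, at -0.09, Tef, at -0.05, and Clock, at -0.02, then did not pass. Smaller changes still passed for Rora (-0.08), Hlf (-0.16), Nr1d2 (-0.12), Cry2 (-0.19), Ciart (-0.27) and Bhlhe40 (-0.34). In that fit the core clock list had 4 higher and 9 lower of 23 and a camera adjusted p = 0.0995 (adjusted p = 0.303 with an estimated correlation). With 1 library left out, Nfil3 0.29 without ZT20 replicate 1 no longer passed. The same held for Cry1 -0.10 without ZT8 replicate 1, -0.14 without ZT20 replicate 1 and -0.15 without ZT20 replicate 2, and for Clock -0.07 without ZT8 replicate 1 and -0.08 without ZT20 replicate 1.

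**Figure D2:**
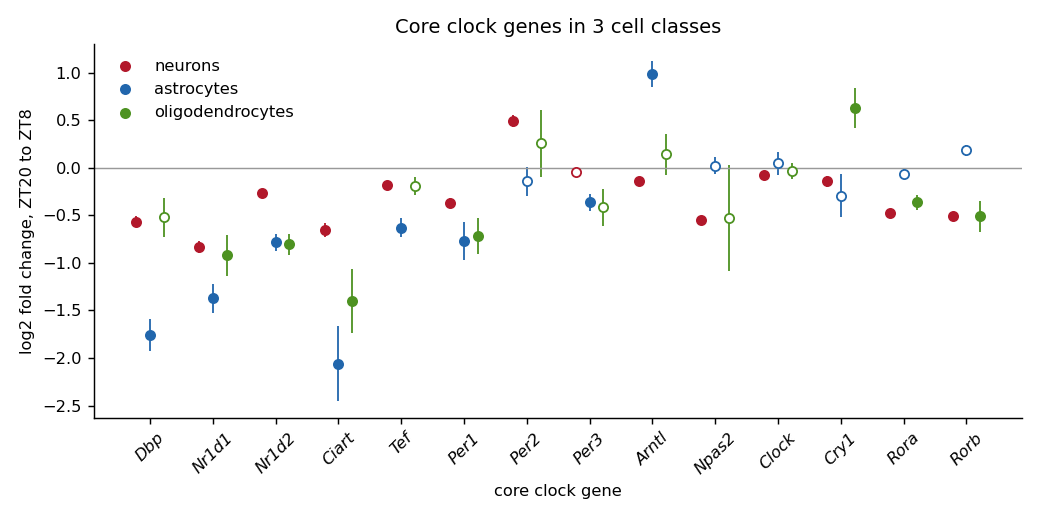
Log2 change of 14 clock genes, ZT20 against ZT8, in neuron-like, astrocyte-like and oligodendrocyte-like nuclei (points with SE bars, 2 libraries per time; filled points have an edgeR adjusted p under 0.05). Nr1d1 lies at -0.84, -1.37 and -0.92 in the 3 classes, and Arntl at -0.14, 0.99 and 0.14.

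Neuropeptide genes had the largest median log2 change of the fixed lists in neuron-like nuclei, with vasopressin (Avp), oxytocin (Oxt), growth hormone-releasing hormone (Ghrh), somatostatin (Sst) and the feeding peptides Cartpt, Npy and Pomc higher at ZT20. Melanin-concentrating hormone (Pmch) transcripts, made by lateral hypothalamic neurons, were nearly confined to ZT20. Prkch and Ntng1, which thalamic neurons express, were lower. Sst rose from 9.38 ± 0.410 to 41.1 ± 2.09 CPM (log2 change 2.08 ± 0.06 SE, edgeR adjusted p = 1.6e-15). Sst (ENSMUSG00000004366) lies on the minus strand of chromosome 16 from 23889573 to 23890958. Erbb4, a neuregulin receptor gene, rose from 574 ± 5.78 to 1074 ± 3.81 CPM (log2 change 0.85 ± 0.02 SE, edgeR adjusted p = 4.9e-17). Erbb4 (ENSMUSG00000062209) lies on the minus strand of chromosome 1 from 68032186 to 69108059. Dgkb, a diacylglycerol kinase gene, rose from 381 ± 10.01 to 684 ± 13.6 CPM (log2 change 0.79 ± 0.02 SE, edgeR adjusted p = 1.2e-15). Dgkb (ENSMUSG00000036095) lies on the plus strand of chromosome 12 from 37817726 to 38634239. Rnf220, a ubiquitin ligase gene, fell from 928 ± 6.65 to 582 ± 5.08 CPM (log2 change -0.73 ± 0.02 SE, edgeR adjusted p = 4.3e-16). Rnf220 (ENSMUSG00000028677) lies on the minus strand of chromosome 4 from 117271463 to 117497052. Prkch, a protein kinase C gene, fell from 153 ± 2.01 to 80.9 ± 2.59 CPM (log2 change -0.97 ± 0.03 SE, edgeR adjusted p = 1.8e-15). Prkch (ENSMUSG00000021108) lies on the plus strand of chromosome 12 from 73584796 to 73778185. Pmch had 2 and 3 UMIs at ZT8 and 802 and 737 at ZT20 in neuron-like nuclei, so its fold change is not given. Pmch (ENSMUSG00000035383) lies on the plus strand of chromosome 10 from 88091072 to 88092375. Further genes with small p were Pcdh7 (0.69 ± 0.02), Ephb1 (1.01 ± 0.03), Hspa5 (0.91 ± 0.03) and Dlk1 (1.48 ± 0.04) higher. Lower were Kcnip4 (-0.66 ± 0.02), Ptpn3 (-0.83 ± 0.02), Synpo2 (-0.83 ± 0.02), Vav3 (-0.75 ± 0.02), Kcnc2 (-0.65 ± 0.02) and Ntng1 (-0.57 ± 0.02) (log2 change ± SE, edgeR adjusted p 1.5e-15 to 5.2e-15). Of the neuropeptide list, Avp (4.66 ± 0.14), Oxt (3.33 ± 0.42), Ghrh (2.73 ± 0.27), Cartpt (2.67 ± 0.13), Tac2 (2.61 ± 0.14) and Npy (2.46 ± 0.12) were higher. Trh (2.40 ± 0.27), Pomc (1.89 ± 0.10), Scg2 (0.79 ± 0.02) and Crh (0.60 ± 0.15) were higher too, and Cck (-0.49 ± 0.04) was lower (adjusted p 2.2e-15 to 0.0296 over these 11 genes). Vip (-0.89 ± 1.01) and Nms (0.29 ± 0.38) did not pass. For each gene called here, both ZT20 libraries lay on one side of both ZT8 libraries. In all, 4196 genes were higher and 4167 lower at ZT20 among 19514 tested. DESeq2 called 4704, and 675 of the edgeR calls exceeded 2-fold. With the same nuclei per neuron cluster, 3260 of the 8363 calls remained in direction and 139 turned. Erbb4 then went to 0.11, Dgkb to 0.14, Rnf220 to -0.08, Kcnip4 to -0.11, Sst to 1.38, Vav3 to 0.07 and Ntng1 to 0.07. PVN-like Sim1-positive neurons had too few nuclei at ZT8 for a test of their own.

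The other lists fixed beforehand gave these counts in neuron-like nuclei, with the member of small p named beside each. The neuropeptide list had 22 higher and 1 lower of 25 and a median log2 change of 1.20 (camera adjusted p = 5.4e-09 with the preset correlation, adjusted p = 0.181 with an estimated correlation). Of 24 neuropeptide genes, 15 passed as higher with the same nuclei per neuron cluster, with a median of 0.62. Receptors of feeding and stress signals had 16 higher and 1 lower of 21, or 16 higher and 2 lower adjusted over the list alone, with the calcitonin receptor Calcr (1.93 ± 0.11), the neuropeptide Y receptor Npy2r (1.22 ± 0.11) and the prolactin receptor Prlr (0.63 ± 0.04) among the higher ones. Calcr is among the leading genes of 2 neuron clusters, with 20 and 23 nuclei at ZT8 and 198 and 164 at ZT20 and with 2 and 1 nuclei at ZT8 and 145 and 140 at ZT20. Given the same nuclei per cluster, the receptor list had 5 higher and 2 lower of 21, with Calcr at 0.06 not passing, Npy2r at 0.61 and Prlr at 0.30. Immediate early genes, which follow neuronal activity, had 9 higher and 1 lower of 20, or 10 higher and 1 lower adjusted over the list alone, among them Nr4a2 (1.16 ± 0.07), Junb (0.64 ± 0.08), Btg2 (0.54 ± 0.08) and Bdnf (0.44 ± 0.05). Their list had a camera adjusted p = 0.0192 with the preset correlation, adjusted p = 0.207 with an estimated correlation. Nr4a2 leads a cluster with 112 and 105 nuclei at ZT8 and 166 and 193 at ZT20, and with the same nuclei per cluster it was 0.71 and its list had 8 of 19 higher. Heat shock genes had 12 of 14 higher. Unfolded protein response genes had 11 higher and 2 lower of 14, or 12 higher and 2 lower adjusted over the list alone, with the chaperones Pdia6 (0.87 ± 0.04), Calr (0.63 ± 0.03) and Hsp90b1 (0.59 ± 0.02). Mitochondrially encoded genes had 12 of 13 higher, with mt-Co3 (0.83 ± 0.03) and mt-Cytb (1.02 ± 0.03). Ribosomal protein genes had 21 of 22 higher, with Rplp1 (0.68 ± 0.03). Reads of the last 2 groups can come from nuclear copies or pseudogenes as well. Ion channel genes had 2 higher and 17 lower of 23, or 3 higher and 18 lower adjusted over the list alone, with the calcium channel gene Cacna1c (-0.56 ± 0.02) and the M-current gene Kcnq3 (-0.43 ± 0.02). Genes of GABA and glutamate transmission had 11 higher and 7 lower of 23, or 11 higher and 8 lower adjusted over the list alone, with Gad2 (0.61 ± 0.03), Gria1 (0.42 ± 0.02) and Grin2a (-0.37 ± 0.02). The same nuclei per cluster gave the ion channel list 4 higher and 9 lower of 23, with Cacna1c at -0.16 and Kcnq3 at -0.06. They gave the transmission list 7 higher and 2 lower of 23, with Gad2 at 0.18, Gria1 at 0.15 and Grin2a at -0.07. Cholesterol synthesis genes had 1 higher and 12 lower of 17, with Hmgcs1 (-0.37 ± 0.03). Myelin genes had 1 higher and 13 lower of 16, and astrocyte function genes 4 higher and 3 lower of 18. Clock outputs had 2 higher and 6 lower of 12. Glucocorticoid response genes had 3 higher and 5 lower of 17, or 4 higher and 5 lower adjusted over the list alone, with the receptor gene Nr3c1 (-0.31 ± 0.03), and nuclear long noncoding genes 2 higher and 5 lower of 9, or 2 higher and 6 lower adjusted over the list alone. The adjusted p of these named genes ran from 1.9e-15 to 7.6e-06, and both ZT20 libraries lay on one side of both ZT8 libraries for each. Median, mean and camera direction differed in sign for the glucocorticoid list (-0.02, 0.06, down) and the astrocyte function list (0.02, -0.01, up). Camera with the preset correlation passed 13 of 18 lists, fry 15, and camera with an estimated correlation 0, with 3 lists at an unadjusted p under 0.05. With droplet background subtracted, the ribosomal protein list had a median of -0.05 and the heat shock list 3 genes higher and 1 lower.

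In glutamatergic-like and thalamic-like neurons the clock genes Nr1d1 and Dbp were lower at ZT20, and in GABAergic-like neurons they did not pass. Glutamatergic-like and thalamic-like neurons share the nuclei of clusters 0, 5, 7, 12 and 21, so the 2 classes are not independent. The glutamatergic minus GABAergic difference of Nr1d1 (-0.35 ± 0.23 SE) did not pass either (edgeR p adjusted over the list alone = 0.258). In GABAergic-like neurons, Hs3st4, which encodes a heparan sulfate sulfotransferase, and Nxph1, which encodes a neurexin ligand, were higher, and the transcription factor genes Sox6 and Meis1 lower. Hs3st4 rose from 194 ± 5.10 to 363 ± 22.1 CPM (log2 change 0.91 ± 0.06 SE, edgeR adjusted p = 3.1e-09). Hs3st4 (ENSMUSG00000078591) lies on the plus strand of chromosome 7 from 123982869 to 124398989. Nxph1 rose from 386 ± 30.5 to 679.8 ± 29.4 CPM (log2 change 0.82 ± 0.06 SE, edgeR adjusted p = 7.3e-09). Nxph1 (ENSMUSG00000046178) lies on the plus strand of chromosome 6 from 8948431 to 9249032. Meis1 fell from 82.2 ± 10.99 to 12.8 ± 2.82 CPM (log2 change -2.70 ± 0.14 SE, edgeR adjusted p = 8.2e-11). Meis1 (ENSMUSG00000020160) lies on the minus strand of chromosome 11 from 18879817 to 19018985. Oxt (3.26 ± 0.16) was higher and Sox6 (-1.54 ± 0.06) and Tmem178 (-1.82 ± 0.11) lower (log2 change ± SE, edgeR adjusted p 1.2e-12 to 3.7e-09). Sox6, Meis1 and Tmem178 are among the leading genes of a GABAergic-like cluster with 62 and 89 nuclei at ZT8 and 6 and 4 at ZT20. Of the 9 clock genes that the naming rule takes in GABAergic-like neurons, only Arntl (0.35 ± 0.10) passed, as higher (edgeR adjusted p = 0.0343). With 1 library left out it did not pass: 0.26 without ZT8 replicate 1, 0.37 without ZT20 replicate 1 and 0.34 without ZT20 replicate 2. Of the others, Cry2 passed as lower and Rorb as higher. Nr1d1 (-0.52 ± 0.20), Per1 (-0.48 ± 0.18) and Dbp (-0.03 ± 0.17) did not pass. In glutamatergic-like neurons, Cartpt (3.88 ± 0.12), Dgkb (1.05 ± 0.03), Erbb4 (0.99 ± 0.03) and Per2 (0.74 ± 0.09) were higher. In the same neurons Col25a1 (-1.14 ± 0.03), Cacna2d3 (-0.80 ± 0.03), Ptpn3 (-0.84 ± 0.03), Npas2 (-0.75 ± 0.04), Dbp (-0.80 ± 0.08), Nr1d1 (-0.87 ± 0.09) and Arntl (-0.23 ± 0.05) were lower (adjusted p 1.2e-17 to 2.2e-04 over these 11 genes). Col25a1 encodes a membrane collagen and Cacna2d3 a calcium channel subunit. In thalamic-like neurons, mt-Co1 (1.02 ± 0.03), mt-Co3 (0.93 ± 0.03), Per2 (0.62 ± 0.09) and Arntl (0.20 ± 0.04) were higher. Rsrp1 (-0.57 ± 0.03), Cntn5 (-0.38 ± 0.02), Nox4 (-0.94 ± 0.06), Nr1d1 (-0.47 ± 0.09), Dbp (-0.49 ± 0.08) and Per3 (-0.18 ± 0.06) were lower there (adjusted p 1.5e-38 to 0.0213 over these 10 genes). Pmch had 1 and 2 UMIs at ZT8 and 205 and 171 at ZT20 in these neurons, which do not make this hormone. Of each gene called, both ZT20 libraries lay on one side of both ZT8 libraries. In GABAergic-like neurons 903 genes were higher and 718 lower at ZT20 among 14668 tested. In glutamatergic-like neurons 3401 were higher and 3407 lower among 17548. In thalamic-like neurons 1813 were higher and 1538 lower among 17011. DESeq2 called 442, 3373 and 1021. In 13 neuron clusters with at least 50 nuclei in every library, a median of 226 genes passed (22 to 967). Passing or not, the log2 change of Nr1d1 was negative in 13 of 13 clusters (median -0.50), Hlf in 13, Dbp and Cry2 in 12 each, and that of Per2 positive in 12 (median 0.33) and Arntl in 9. Over all genes, edgeR called Dbp in 2 clusters, Hlf and Arntl in 1 each, all thalamic-like, and Per2 in 2. Adjusted over the list alone, Per2 passed in 3 clusters, Nr1d1 and Cry2, which did not pass over all genes, in 1 each, and Rorb was higher in 3 and lower in 2. With the same nuclei per cluster, 350 of 1621 calls remained in GABAergic-like and 1917 of 6808 in glutamatergic-like neurons. In GABAergic-like neurons Meis1 was then -0.10, Hs3st4 0.13, Nxph1 0.28 and Arntl 0.39 without passing, and Tmem178 -0.86 still passed. Sox6 turned to 0.10, glutamatergic Dgkb to -0.01 and glutamatergic Arntl to 0.11. Thalamic-like Per3 -0.16 without ZT8 replicate 1, -0.21 without ZT20 replicate 1 and -0.16 without ZT20 replicate 2 did not pass.

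**Figure D3:**
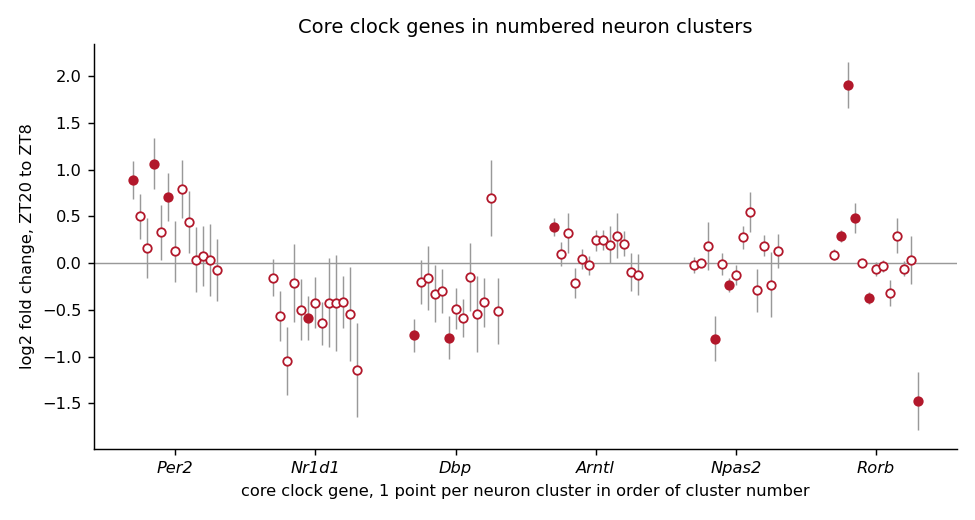
Log2 change of Per2, Nr1d1, Dbp, Arntl, Npas2 and Rorb, ZT20 against ZT8, in 13 neuron clusters (points with SE bars; filled points pass an adjusted p of 0.05 over the core clock list alone). Nr1d1 lies below 0 in 13 clusters and Per2 above 0 in 12, while Rorb runs from -1.48 to 1.90. Clusters 0, 1, 4, 5, 6, 7 and 12 are thalamic-like.

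In astrocyte-like nuclei the E-box driven genes Dbp, Nr1d1, Nr1d2, Tef and Ciart were lower at ZT20, and Arntl, which REV-ERB represses, was higher. Hif3a and Fkbp5, which glucocorticoids induce, were lower, and the glutamate receptor gene Grm3 and the polyamine acetyltransferase gene Sat1 higher. Region and time cannot be told apart in glia, which were not matched. Dbp fell from 104 ± 11.5 to 29.9 ± 7.24 CPM (log2 change -1.76 ± 0.17 SE, edgeR adjusted p = 6.1e-09). Nr1d1 fell from 92.5 ± 1.31 to 34.4 ± 0.854 CPM (log2 change -1.37 ± 0.15 SE, edgeR adjusted p = 1.8e-07). Nr1d2 fell from 220.3 ± 0.191 to 123 ± 3.89 CPM (log2 change -0.79 ± 0.09 SE, edgeR adjusted p = 6.3e-07). Nr1d2 (ENSMUSG00000021775) lies on the minus strand of chromosome 14 from 18204054 to 18239127. Arntl rose from 52.6 ± 3.68 to 101 ± 2.86 CPM (log2 change 0.99 ± 0.14 SE, edgeR adjusted p = 7.4e-06). Arntl (ENSMUSG00000055116) lies on the plus strand of chromosome 7 from 113207465 to 113314126. Tef fell from 191 ± 2.47 to 119.5 ± 12.8 CPM (log2 change -0.63 ± 0.10 SE, edgeR adjusted p = 5.9e-05). Tef (ENSMUSG00000022389) lies on the plus strand of chromosome 15 from 81802421 to 81826863. Hif3a fell from 150.0 ± 16.1 to 73.03 ± 3.38 CPM (log2 change -0.98 ± 0.12 SE, edgeR adjusted p = 6.8e-07). Hif3a (ENSMUSG00000004328) lies on the minus strand of chromosome 7 from 17031507 to 17062427. Grm3 rose from 522 ± 36.7 to 797 ± 2.53 CPM (log2 change 0.66 ± 0.06 SE, edgeR adjusted p = 5.8e-09). Grm3 (ENSMUSG00000003974) lies on the minus strand of chromosome 5 from 9485541 to 9725170. Fat3, an atypical cadherin gene, rose from 517 ± 15.4 to 831 ± 26.2 CPM (log2 change 0.73 ± 0.06 SE, edgeR adjusted p = 2.2e-10). Fat3 (ENSMUSG00000074505) lies on the minus strand of chromosome 9 from 15910189 to 16501285. Sat1 rose from 207 ± 33.1 to 365 ± 7.65 CPM (log2 change 0.87 ± 0.08 SE, edgeR adjusted p = 8.4e-09). Sat1 (ENSMUSG00000025283) lies on the minus strand of chromosome X from 155213132 to 155216449. Other genes with small p were Wdr17 (0.57 ± 0.05) higher and Mpp6 (-0.50 ± 0.06) and Nrxn3 (-0.48 ± 0.06) lower. Ciart (-2.06 ± 0.39), Bhlhe40 (-0.71 ± 0.16), Hlf (-0.40 ± 0.10), Per1 (-0.78 ± 0.20), Per3 (-0.37 ± 0.09), Fkbp5 (-1.29 ± 0.31) and Usp2 (-0.59 ± 0.14) were also lower (log2 change ± SE, edgeR adjusted p 6.4e-04 to 0.0137). With 1 library left out these did not pass: Ciart -1.48 without ZT20 replicate 1, Bhlhe40 -0.51 without ZT20 replicate 1 and Hlf -0.27 without ZT20 replicate 2. The same held for Per1 -0.66 without ZT8 replicate 1 and -0.55 without ZT20 replicate 1 and Per3 -0.41 without ZT20 replicate 1 and -0.32 without ZT20 replicate 2. It also held for Fkbp5 -1.42 without ZT20 replicate 1 and -1.17 without ZT20 replicate 2, and for Usp2 -0.52 without ZT8 replicate 1, -0.73 without ZT20 replicate 1 and -0.47 without ZT20 replicate 2. Both ZT20 libraries lay on one side of both ZT8 libraries for each gene called. The core clock list had 1 higher and 9 lower of 23, or 2 higher and 9 lower adjusted over the list alone (camera adjusted p = 5.6e-05 with the preset correlation, adjusted p = 0.0999 with an estimated correlation). The PER, REV-ERB and DBP arm had 9 of 12 lower, with a median of -0.67 (camera adjusted p = 8.5e-08 with the preset correlation, adjusted p = 0.0999 with an estimated correlation), and the BMAL1 arm 1 of 5 higher. Astrocyte function genes had 3 higher and 2 lower of 18, or 5 higher and 2 lower adjusted over the list alone, with Apoe (0.38 ± 0.05) and Slc7a11 (0.40 ± 0.06) higher and the phagocytic receptor gene Mertk (-0.38 ± 0.06) lower. Cholesterol synthesis genes had 6 of 17 lower, or 8 lower adjusted over the list alone, with Hmgcs1 (-0.61 ± 0.10) and Msmo1 (-0.43 ± 0.08). Glucocorticoid response genes had 4 of 15 lower, or 6 lower adjusted over the list alone, and clock outputs 3 of 10 lower, or 1 higher and 5 lower adjusted over the list alone. Myelin genes had 7 of 15 lower, or 8 lower adjusted over the list alone. Ion channel genes had 4 of 23 lower, or 6 lower adjusted over the list alone, with Kcnq3 (-0.75 ± 0.10). Heat shock genes had 5 of 11 higher, or 6 higher adjusted over the list alone, but with droplet background subtracted their direction turned (camera adjusted p = 0.895). Unfolded protein response genes had 6 of 12 higher, or 9 higher adjusted over the list alone, with Hspa5 (0.94 ± 0.11). Mitochondrially encoded genes had 8 of 13 higher, or 12 higher adjusted over the list alone. Ribosomal protein genes had 15 of 22 higher, or 18 higher adjusted over the list alone. With background subtracted the ribosomal median went from 0.41 to 0.11 (camera adjusted p = 0.873), and 1 of 9 mitochondrially encoded genes then passed as higher. Nuclear long noncoding genes had 1 higher and 1 lower of 9, or 1 higher and 4 lower adjusted over the list alone. Genes of GABA and glutamate transmission had 3 higher and 2 lower of 23, or 3 higher and 5 lower adjusted over the list alone, with a median of 0.02, a mean of 0.00 and a camera direction of down. Feeding receptors had a median of -0.08, a mean of 0.35 and a camera direction of up. Oxt had 38 and 52 UMIs at ZT8 and 475 and 404 at ZT20 in astrocyte-like nuclei. In unnamed nuclei with few UMIs it had 99.8 and 177 CPM at ZT8 and 1393 and 1265 CPM at ZT20, so no expression by glia is read from neuropeptide transcripts in them. Of 12078 genes tested, 425 were higher and 271 lower at ZT20. DESeq2 called 142, and 111 edgeR calls exceeded 2-fold. With droplet background subtracted, 132 of the 696 calls remained, and Ciart (-2.63), Bhlhe40 (-0.80), Hlf (-0.48), Per1 (-0.92) and Per3 (-0.34) did not pass, with log2 changes about as large.

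**Figure D4:**
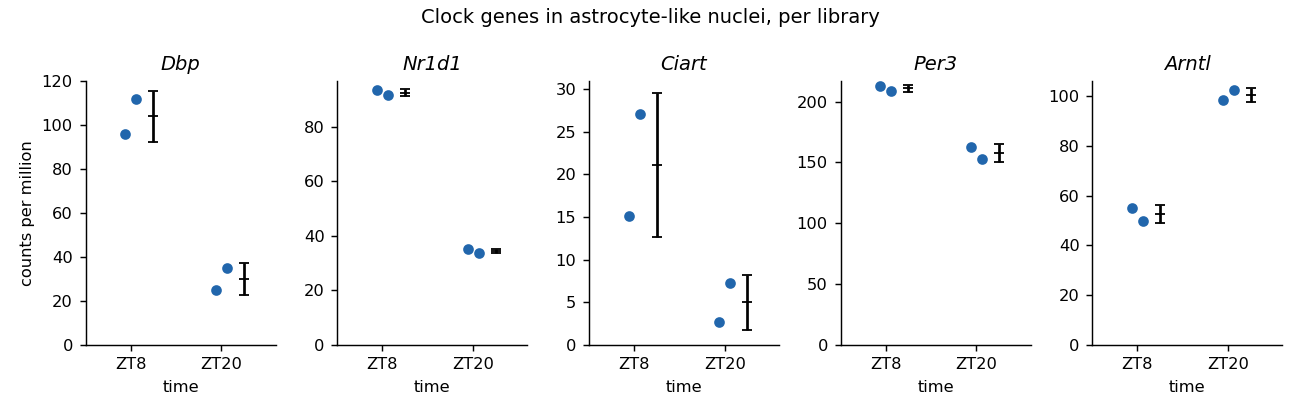
CPM of Dbp, Nr1d1, Ciart, Per3 and Arntl in astrocyte-like nuclei, 1 point per library with the mean ± SD of each time. Both ZT20 libraries lie below both ZT8 libraries for Dbp, with means of 104 CPM at ZT8 and 29.9 CPM at ZT20.

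In oligodendrocyte-like nuclei, the REV-ERB genes Nr1d1 and Nr1d2 were lower at ZT20, and Ptgds, whose product makes the sleep-promoting prostaglandin D2, and Robo1, the receptor gene of Slit ligands, were higher. Kirrel3 and Tenm2, which encode synaptic adhesion proteins, and Zbtb16 and Sgk1, which glucocorticoids induce, were lower. Nr1d2 fell from 115 ± 3.56 to 65.2 ± 2.81 CPM (log2 change -0.80 ± 0.11 SE, edgeR adjusted p = 4.8e-09). Nr1d1 fell from 31.2 ± 1.22 to 16.2 ± 0.389 CPM (log2 change -0.92 ± 0.21 SE, edgeR adjusted p = 9.0e-04). Ptgds rose from 1265 ± 5.33 to 2410.2 ± 85.1 CPM (log2 change 0.95 ± 0.04 SE, edgeR adjusted p = 3.4e-53). Ptgds (ENSMUSG00000015090) lies on the minus strand of chromosome 2 from 25466709 to 25470046. Robo1 rose from 498 ± 10.9 to 868 ± 1.19 CPM (log2 change 0.83 ± 0.05 SE, edgeR adjusted p = 6.3e-34). Robo1 (ENSMUSG00000022883) lies on the plus strand of chromosome 16 from 72308306 to 73046095. Kirrel3 fell from 1521 ± 53.4 to 821 ± 45.9 CPM (log2 change -0.87 ± 0.04 SE, edgeR adjusted p = 2.1e-41). Kirrel3 (ENSMUSG00000032036) lies on the plus strand of chromosome 9 from 34485894 to 35036716. Zbtb16 fell from 135 ± 9.02 to 73.4 ± 1.59 CPM (log2 change -0.85 ± 0.11 SE, edgeR adjusted p = 8.0e-11). Zbtb16 (ENSMUSG00000066687) lies on the minus strand of chromosome 9 from 48654297 to 48836222. Sgk1 fell from 122 ± 17.6 to 83.2 ± 2.14 CPM (log2 change -0.51 ± 0.11 SE, edgeR adjusted p = 1.7e-04). Sgk1 (ENSMUSG00000019970) lies on the plus strand of chromosome 10 from 21882184 to 21999903. Other genes with small p were Mpzl1 (1.11 ± 0.08), Lrrc4c (0.54 ± 0.04) and Usp31 (0.89 ± 0.07) higher. Lower were Luc7l2 (-0.66 ± 0.05), Ank3 (-0.46 ± 0.04), Tenm2 (-0.79 ± 0.07), St6galnac3 (-0.43 ± 0.04), Kcnip4 (-0.66 ± 0.06), Auts2 (-0.51 ± 0.05), Nckap5 (-0.95 ± 0.09) and Rora (-0.37 ± 0.08) (log2 change ± SE, edgeR adjusted p 9.8e-26 to 5.1e-04). Myelin genes moved both ways, with 3 higher and 4 lower of 16, among them Cnp (-0.44 ± 0.06), Opalin (-0.33 ± 0.05), Cldn11 (-0.26 ± 0.05) and Mog (-0.21 ± 0.04). Lower clock genes were also Ciart (-1.40 ± 0.33), Per1 (-0.72 ± 0.19), Rorb (-0.51 ± 0.16), Hlf (-0.47 ± 0.13) and Bhlhe40 (-0.80 ± 0.25), and Cry1 (0.63 ± 0.21) was higher (adjusted p 0.00124 to 0.0376). Each of these failed to pass in at least 1 fit with a library left out. Such fits gave Ciart -1.04 without ZT8 replicate 2 and -1.11 without ZT20 replicate 1 and Per1 -0.50 without ZT8 replicate 2 and -0.68 without ZT20 replicate 2. They also gave Rorb -0.51 without ZT8 replicate 1, -0.52 without ZT8 replicate 2 and -0.29 without ZT20 replicate 1 and Hlf -0.41 without ZT8 replicate 2 and -0.41 without ZT20 replicate 1. The last were Bhlhe40 -0.83 without ZT8 replicate 1, -0.76 without ZT8 replicate 2 and -0.60 without ZT20 replicate 2, and Cry1 0.56 without ZT8 replicate 1, 0.70 without ZT8 replicate 2, 0.52 without ZT20 replicate 1 and 0.71 without ZT20 replicate 2. Both ZT20 libraries lay on one side of both ZT8 libraries for each gene called. Arntl (0.14 ± 0.22) and Per2 (0.25 ± 0.36) did not pass. Dbp (-0.52 ± 0.21) and Cry2 (-0.33 ± 0.13) passed only when adjusted over the list alone (edgeR adjusted p = 0.0276 and 0.0314). The core clock list had 1 higher and 8 lower of 22, or 1 higher and 10 lower adjusted over the list alone (camera adjusted p = 0.00109 with the preset correlation, adjusted p = 0.373 with an estimated correlation). Its camera adjusted p with the preset correlation was 0.0633 without ZT20 replicate 2 and 0.119 with droplet background subtracted. The PER, REV-ERB and DBP arm had 6 of 12 lower, or 10 lower adjusted over the list alone (camera adjusted p = 9.4e-05 with the preset correlation, adjusted p = 0.318 with an estimated correlation), and the BMAL1 arm 1 of 5 higher. Heat shock genes had 9 of 12 higher, or 11 higher adjusted over the list alone, with Hsp90ab1 (0.45 ± 0.05). Mitochondrially encoded genes had 10 of 13 higher, or 11 higher adjusted over the list alone, with mt-Co1 (0.70 ± 0.06). Ribosomal protein genes had 17 of 22 higher, or 19 higher adjusted over the list alone. With background subtracted 1 of 22 ribosomal genes passed, their median going from 0.47 to 0.23, and 3 of 10 mitochondrially encoded genes passed. Unfolded protein response genes had 6 of 13 higher, and ion channel genes 8 of 23 lower, or 9 lower adjusted over the list alone. GABA and glutamate transmission genes had 2 higher and 7 lower of 23, or 3 higher and 9 lower adjusted over the list alone, and glucocorticoid response genes 4 of 15 lower. Neuropeptide genes had 11 higher and 1 lower of 19, or 14 higher and 1 lower adjusted over the list alone, with Avp at 1 and 13 UMIs at ZT8 and 98 and 70 at ZT20. Feeding receptors had 1 higher and 1 lower of 7, or 2 higher and 2 lower adjusted over the list alone, with a median of -0.07, a mean of 0.14 and a camera direction of down. Of 12123 genes tested, 658 were higher and 574 lower at ZT20. DESeq2 called 294, and 154 edgeR calls exceeded 2-fold. With droplet background subtracted, 210 of the 1232 calls remained, and Rora turned to 0.18. Free RNA may lower neuronal genes such as Kcnip4, which leads thalamic-like clusters.

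OPC-like nuclei, the dividing precursors of oligodendrocytes, and microglia-like nuclei, the immune cells of the brain, were fewer, and fewer genes passed in them, where the tests recover fewer changes. In OPC-like nuclei, Epb41l2 (-0.85 ± 0.12) and Gria1 (-0.73 ± 0.14), the genes of a membrane skeleton protein and a glutamate receptor subunit, were lower at ZT20 (log2 change ± SE, edgeR adjusted p 2.5e-06 to 0.00113). Arntl (1.20 ± 0.31) was higher and Per3 (-0.70 ± 0.19) lower in both ZT20 libraries, but neither passed with any library left out (Arntl 0.97 to 1.44, Per3 -0.79 to -0.62). Dbp (-1.11 ± 0.33), Ciart (-1.48 ± 0.56) and Per2 (-0.62 ± 0.24) passed, as lower, only adjusted over the list alone (edgeR adjusted p = 0.00667, 0.0414 and 0.0444). In microglia-like nuclei, Ctss (0.71 ± 0.11), the gene of the lysosomal protease cathepsin S, was higher, as was Rpl37 (0.96 ± 0.15). Ctss (ENSMUSG00000038642) lies on the plus strand of chromosome 3 from 95526786 to 95556403. Auts2 (-1.18 ± 0.23) and Klf12 (-0.62 ± 0.13) were lower (adjusted p 1.6e-04 to 0.00522). Nr1d2 (-0.97 ± 0.28) passed only adjusted over the list alone (edgeR adjusted p = 0.0165). Oxt was called higher in both classes, at 11 and 24 UMIs at ZT8 and 186 and 150 at ZT20 in OPC-like and 10 and 16 UMIs at ZT8 and 140 and 130 at ZT20 in microglia-like nuclei. Both ZT20 libraries lay on one side of both ZT8 libraries for each gene called. In OPC-like nuclei 103 genes were higher and 42 lower at ZT20 among 10167 tested, with 11 by DESeq2. With 1 library left out, 64 without ZT8 replicate 1, 70 without ZT8 replicate 2 and 93 without ZT20 replicate 1 passed there. In microglia-like nuclei 39 genes were higher and 14 lower at ZT20 among 7048 tested, with 1 by DESeq2. There, 158 without ZT8 replicate 1, 22 without ZT20 replicate 1 and 17 without ZT20 replicate 2 passed, and without ZT8 replicate 1 the balance of directions turned, with 54 higher and 104 lower. With 1 library left out, Auts2 -1.02 without ZT8 replicate 2 and -0.91 without ZT20 replicate 1 and Klf12 -0.54 without ZT8 replicate 2 and -0.55 without ZT20 replicate 2 did not pass in microglia-like nuclei. With droplet background subtracted, 29 of 145 OPC-like and 2 of 53 microglia-like calls remained.

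Whether the change from ZT8 to ZT20 differed between classes was tested directly. The change of Arntl was higher in astrocyte-like than in neuron-like nuclei, Dbp and Ciart fell further in astrocyte-like nuclei, and Rorb, an activator of Arntl, moved apart between classes. Astrocyte minus neuron log2 differences ± SE, with edgeR p adjusted over the list alone, were Arntl (1.14 ± 0.14, adjusted p = 1.2e-14), Dbp (-1.18 ± 0.18, adjusted p = 3.7e-10) and Ciart (-1.41 ± 0.39, adjusted p = 7.3e-04). Nuclei of both classes also differed in Nr1d1 (-0.53 ± 0.18, adjusted p = 0.00853), Rorb (0.70 ± 0.07, adjusted p = 1.1e-21) and Per2 (-0.62 ± 0.17, adjusted p = 7.3e-04). Of the core clock list, 12 of 24 genes passed adjusted over the list alone and 10 over all genes for neurons and astrocytes, 3 and 2 for neurons and oligodendrocytes, 6 and 4 for astrocytes and oligodendrocytes, and 9 and 8 for GABAergic and glutamatergic neurons. Oligodendrocyte-like nuclei differed from neuron-like nuclei in Nr1d2 (-0.55 ± 0.12, adjusted p = 8.1e-05) and Cry1 (0.76 ± 0.22, adjusted p = 0.00643). They differed from astrocyte-like nuclei in Dbp (1.21 ± 0.28, adjusted p = 1.6e-04) and Arntl (-0.88 ± 0.26, adjusted p = 0.0046). Glutamatergic minus GABAergic differences were Rorb (-0.94 ± 0.08, adjusted p = 1.1e-31), Npas2 (-0.85 ± 0.11, adjusted p = 2.8e-14), Dbp (-0.77 ± 0.20, adjusted p = 3.8e-04) and Per2 (0.58 ± 0.18, adjusted p = 0.00443). Over all genes, the change differed for 625 of 19308 genes between neurons and astrocytes (371 without ZT8 replicate 1, 414 without ZT8 replicate 2, 339 without ZT20 replicate 1 and 388 without ZT20 replicate 2). It differed for 812 of 18834 genes between neurons and oligodendrocytes (415 without ZT20 replicate 1 and 487 without ZT20 replicate 2). Between astrocytes and oligodendrocytes it differed for 216 of 12972 genes (106 without ZT8 replicate 1, 71 without ZT8 replicate 2, 98 without ZT20 replicate 1 and 86 without ZT20 replicate 2), and between GABAergic and glutamatergic neurons for 1882 of 17392 genes (1192 without ZT20 replicate 2). Subtracting droplet background from neurons and astrocytes left Nr1d1 (-0.58), Ciart (-2.01), Per2 (-0.68) and Per3 (-0.33) not passing over the list alone, with differences about as large. With the same nuclei per neuron cluster, Arntl, Dbp, Ciart, Nr1d1, Nr1d2, Tef, Per2 and Rorb still differed between neurons and astrocytes over the list alone and Npas2, Cry2, Rora and Per3 did not, while Per1, Hlf and Csnk1e newly passed, the difference of Rorb going from 0.70 to 0.23. Arntl itself turned to 0.12 in neuron-like nuclei in that fit, and its astrocyte minus neuron difference was 0.87 (edgeR p adjusted over the list alone = 3.7e-07). Only Rorb still differed between GABAergic and glutamatergic neurons (adjusted p = 0.00805). With droplet background subtracted, 80, 62 and 0 genes differed for the 3 pairs with glia, where the last pair had 705 genes at an unadjusted p under 0.05 by edgeR, the only tool run for these differences.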

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

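The fits with the same nuclei per neuron cluster, with droplet background subtracted and with thalamic-like neurons as a class were chosen after seeing the data, and the expected outcomes of the tests of explanations were written before their results. For mitochondrial and ribosomal genes, the test of free RNA was divided by list and class after the results had been seen.

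Clock genes did not change alike in all classes: the REV-ERB genes, Dbp, Arntl and the ROR genes Rora and Rorb moved by different amounts from ZT8 to ZT20. For 30 gene and class pairs the edgeR test of the difference itself passed, adjusted over the list alone, and the values are log2 differences. Between neurons and astrocytes, the values for astrocytes minus neurons were Rorb 0.70, Arntl 1.14, Rora 0.42, Npas2 0.58 and Cry2 0.42 on the positive side and Dbp -1.18, Nr1d2 -0.51, Tef -0.44, Per2 -0.62, Ciart -1.41, Per3 -0.30 and Nr1d1 -0.53 on the negative side (adjusted p 1.1e-21 to 0.00853). Between neurons and oligodendrocytes, the values for oligodendrocytes minus neurons were Cry1 0.76 and Bhlhe41 0.51 on the positive side and Nr1d2 -0.55 on the negative side (adjusted p 8.1e-05 to 0.0427). Between astrocytes and oligodendrocytes, the values for oligodendrocytes minus astrocytes were Dbp 1.21, Tef 0.40 and Cry1 0.88 on the positive side and Rorb -0.72, Rora -0.34 and Arntl -0.88 on the negative side (adjusted p 1.6e-04 to 0.0221). Between GABAergic neurons and glutamatergic neurons, the values for glutamatergic neurons minus GABAergic neurons were Per2 0.58 on the positive side and Rorb -0.94, Rora -0.58, Npas2 -0.85, Arntl -0.58, Hlf -0.46, Dbp -0.77, Clock -0.25 and Tef -0.23 on the negative side (adjusted p 1.1e-31 to 0.0243). With the same nuclei per neuron cluster, 1 of 9 differences still passed for GABAergic and glutamatergic neurons, 8 of 12 for neurons and astrocytes and 2 of 3 for neurons and oligodendrocytes. Others passed by edgeR only there, namely Per1 (-0.68, adjusted p = 0.00495), Hlf (-0.24, adjusted p = 0.0477) and Csnk1e (-0.46, adjusted p = 0.0373) between neurons and astrocytes. Between neurons and oligodendrocytes edgeR newly passed Per1 (-0.65, adjusted p = 0.00942), Ciart (-1.15, adjusted p = 0.0101), Rora (-0.31, adjusted p = 0.0101) and Rorb (-0.49, adjusted p = 0.0162). The one left for GABAergic and glutamatergic neurons was Rorb (-0.37, adjusted p = 0.00805), while Npas2 was -0.19, Dbp -0.33 and Rora -0.18, and Hlf turned to 0.20. Between neurons and astrocytes Rora was then 0.02 and Npas2 0.09. After subtraction of droplet background, 0 of 6 still passed by edgeR for astrocytes and oligodendrocytes, where Arntl, Tef and Cry1 had unadjusted p under 0.05 and Rora turned to 0.18. There the differences of Dbp (1.63), Arntl (-1.03), Cry1 (1.11) and Tef (0.47) stayed as large, with wider SE of 1.32, 0.31, 0.41 and 0.18. In that fit 8 of 12 still passed for neurons and astrocytes, where Nr1d1, Ciart, Per2 and Per3 did not, 1 of 3 for neurons and oligodendrocytes and 7 of 9 for GABAergic and glutamatergic neurons.

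Neuropeptide genes such as Avp, Oxt and Cartpt were higher at ZT20 in neurons, with a median log2 change of 1.52 over the 23 called genes. With background subtracted the median was 1.53, with 17 genes higher and 1 lower of 22 tested, which speaks against free RNA in the droplets. With the same nuclei per neuron cluster it fell to 0.62, 40.9% of the value before, and 15 of 22 genes were still higher. A different mix of neuron clusters in the ZT20 pools, for example from where the punch was placed, may thus account for a large part of the change. How large a part cannot be told. Neuropeptide genes were not left out of the clustering, and Avp, Oxt, Cartpt and Trh were among the leading genes of the Sim1-positive cluster. Drawing the same nuclei per cluster can therefore also remove a change of these genes. What is left stays open between time of day, a mix finer than the clusters and free RNA, since background was not subtracted from that fit.

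Neuropeptide genes, Oxt among them, were also higher at ZT20 in astrocytes, oligodendrocytes and microglia. Their log2 change lay near that in unnamed nuclei with few UMIs, with a median distance of 0.101 over 11 genes in astrocytes, 0.204 over 12 in oligodendrocytes and 0.283 over 5 in microglia, although single genes lay up to 1.38, 0.870 and 0.604 away. Free RNA in the droplets, released by peptide-making neurons, may therefore account for the signal in glia. Expression by the glia themselves at night was not tested.

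Mitochondrially encoded genes such as mt-Co3 and ribosomal protein genes such as Rplp1 were higher at ZT20 in all nuclei, neurons, astrocytes and oligodendrocytes. Subtracting background left 126% of the mitochondrial median in neurons, with 9 of 13 genes called higher, which speaks against free RNA in the droplets there. It left -12.6, 26.5 and 48.4% of the ribosomal median in neurons, astrocytes and oligodendrocytes, so free RNA may account for that part. Of the mitochondrial median it left 80.5% in astrocytes and 294% in oligodendrocytes, where only 9 and 10 of 13 genes kept enough counts, so free RNA and a change in the nuclei cannot be told apart in these glia. The 20% of protein-coding genes with the shortest spans lay above the 20% with the longest by 0.143, 0.12 and 0.140 in median log2 change, so more cytoplasmic RNA kept with the ZT20 nuclei is a candidate explanation, and a higher level at night stays open.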

How the results depend on the processing

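The DESeq2 test, the estimated correlation, the stricter nuclei filter, thinning, kept doublets, Leiden resolution 2, the fit without a low-count filter, the replicate block and the fits with a library left out were planned. The same nuclei per neuron cluster and the subtracted droplet background were chosen after seeing the data. Of the values that answer a comparison, 289 kept their direction and side of the threshold or stayed within the tolerance, 61 moved, 11 no longer passed and 7 turned. Of those for single genes and lists, 5965 stayed, 415 no longer passed, 33 newly passed, 70 moved and 23 turned. Of the named called genes, 86 of 89 in neurons, 42 of 65 in astrocytes and 48 of 66 in oligodendrocytes passed with each library left out in turn. Depth limits the smaller classes: the sums of microglia held 285189 to 334162 UMIs per library and those of neurons 35048544 to 41356120. Except where stated, the cause was not tested.

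DESeq2 called 6426 genes in all nuclei (edgeR 10035), 4704 in neurons (8363), 3373 in glutamatergic (6808), 442 in GABAergic (1621) and 1021 in thalamic-like neurons (3351). It called 142 in astrocytes (696), 294 in oligodendrocytes (1232), 11 in OPCs (145), 1 in microglia (53) and a median of 34 over the numbered neuron clusters (226). With an estimated correlation, camera passed 0 lists in all nuclei, neurons, astrocytes and oligodendrocytes (13, 13, 12 and 8 with the preset one, and 15, 15, 13 and 8 by fry), with 2, 3, 9 and 3 at an unadjusted p under 0.05. The core clock list then had adjusted p of 0.197, 0.181, 0.0999 and 0.373, and the PER, REV-ERB and DBP arm 0.197, 0.181, 0.0999 and 0.318.

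With the same nuclei per neuron cluster, which leaves fewer nuclei, 3939 genes passed in neurons, 2345 in glutamatergic, 402 in GABAergic and 2162 in thalamic-like neurons, and the change differed for 202 genes between GABAergic and glutamatergic neurons (1882 before) and 230 between neurons and astrocytes (625). The core clock list had a camera adjusted p = 0.0995 and the BMAL1 arm 0.527 in neurons. These log2 changes turned in neurons: Arntl from -0.14 to 0.12, Cry1 from -0.14 to 0.012, Gabbr2 from -0.41 to 0.051, Ntng1 from -0.57 to 0.069, Usp2 from -0.33 to 0.0045, Vav3 from -0.75 to 0.066 and Zbtb16 from 0.41 to -0.18. Those in glutamatergic neurons were Arntl from -0.23 to 0.11, Dgkb from 1.05 to -0.0052 and Per1 from -0.33 to 0.020, and in GABAergic neurons Sox6 from -1.54 to 0.098. The glutamatergic minus GABAergic difference of Hlf turned from -0.46 to 0.20.

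With droplet background subtracted, 1059 genes passed in GABAergic neurons, 145 in astrocytes, 223 in oligodendrocytes, 34 in OPCs, 2 in microglia and a median of 120 over the numbered clusters. The change differed for 80 genes between neurons and astrocytes, 62 between neurons and oligodendrocytes and 0 between astrocytes and oligodendrocytes by edgeR (705 at an unadjusted p under 0.05). Camera passed 3 lists in oligodendrocytes, where the core clock list had an adjusted p = 0.119. Turned in direction were the ribosomal protein list in neurons (camera adjusted p = 0.474) and, in astrocytes, the heat shock list (0.895) and the neuropeptide list (0.419), the latter by construction, since the scaling uses neuropeptide genes. Single genes turned in neurons, Aldoc from 0.56 to -0.81, Hspa8 from 0.28 to -0.095, Mt1 from 0.29 to -3.38 and Rps24 from 0.54 to -0.063, in astrocytes, Hsp90aa1 from 0.25 to -0.85 and Hsp90ab1 from 0.32 to -0.27, and in oligodendrocytes, Rora from -0.37 to 0.18. The oligodendrocyte minus astrocyte difference of Rora turned from -0.34 to 0.18.

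With at least 1000 genes and at most 1% mitochondrial UMIs, 3064 genes passed in GABAergic neurons and 123 in microglia. Clusters were formed and named anew in this setting. The GABAergic class went from 367, 392, 472 and 458 nuclei (ZT8 then ZT20) to 488, 503, 939 and 949. A stricter filter cannot add nuclei, so the higher GABAergic count and share come with a changed class. The ZT20 minus ZT8 differences in share were then 9.90 points for GABAergic neurons, 7.91 for neurons, 0.397 for astrocytes and -0.137 for unnamed nuclei (from 15.5), which this filter removes by construction. With doublets kept, 2464 genes passed in GABAergic neurons and their share difference was 2.47, against 1.13 at Leiden resolution 2 and -0.352 before. Clusters were named anew there too. The GABAergic class held 428, 448, 775 and 826 nuclei (ZT8 then ZT20) with doublets kept and 398, 458, 641 and 658 at resolution 2. Thinning to the smallest library left 80 genes in OPCs and gave 80 in microglia, and without a low-count filter the median over numbered clusters was 377. RLE size factors turned none of the values that answer a comparison. With the replicate number as a block, 91 genes passed in microglia; the labels do not pair libraries, and over genes the replicate deviations at both times correlated by -0.0675 to 0.00369, genes not being independent.

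With 1 library left out, the genes passing ran from 168 (without ZT20 replicate 1) to 551 (without ZT20 replicate 2) in astrocytes, 753 (without ZT20 replicate 1) to 925 (without ZT8 replicate 1) in oligodendrocytes, with 819 without ZT8 replicate 2. They ran from 64 (without ZT8 replicate 1) to 157 (without ZT20 replicate 2) in OPCs, 17 (without ZT20 replicate 2) to 158 (without ZT8 replicate 1) in microglia and 1009 (without ZT20 replicate 2) to 1695 (without ZT8 replicate 1) in GABAergic neurons. Genes whose change differed ran from 339 (without ZT20 replicate 1) to 414 (without ZT8 replicate 2) for neurons and astrocytes, 415 (without ZT20 replicate 1) to 582 (without ZT8 replicate 1) for neurons and oligodendrocytes. They ran from 71 (without ZT8 replicate 2) to 106 (without ZT8 replicate 1) for astrocytes and oligodendrocytes and 1192 (without ZT20 replicate 2) to 1410 (without ZT20 replicate 1) for GABAergic and glutamatergic neurons. The camera adjusted p of the core clock list in oligodendrocytes ran from 4.4e-04 (without ZT8 replicate 1) to 0.0633 (without ZT20 replicate 2). That of the BMAL1 arm ran from 0.119 (without ZT20 replicate 2) to 0.965 (without ZT20 replicate 1) in oligodendrocytes and 0.802 (without ZT8 replicate 2) to 0.883 (without ZT20 replicate 2) in all nuclei. The share difference of GABAergic neurons ran from -0.757 (without ZT20 replicate 1) to 0.0518 (without ZT20 replicate 2). A fit with fewer libraries has less power, which lowers counts by construction; the cause of higher counts was not tested.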

Other observations

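The observations below were made after the data had been seen, and no explanation was tested for them. A cluster led by the smooth muscle genes Acta2, Myh11 and Tagln, which stayed unnamed by the marker rule, held 82 and 82 nuclei in the ZT8 libraries and 2 and 3 in the ZT20 libraries. A cluster led by haemoglobin genes held 16 and 14 nuclei at ZT8 and 21 and 19 at ZT20. 5 neuron clusters with at most 3 nuclei in each ZT8 library held 7 and 7 nuclei at ZT8 and 315 and 331 at ZT20. 2 other neuron clusters, one led by Sox6 and Meis1 and the other by the cholinergic genes Chat and Slc5a7, held 75 and 95 nuclei at ZT8 and 7 and 7 at ZT20. Pmch had 0 and 2 UMIs at ZT8 and 580 and 1100 at ZT20 in unnamed nuclei with few UMIs. Mitochondrial genes took 0.1003 and 0.103% of UMIs in the ZT8 libraries and 0.180 and 0.184% in the ZT20 libraries.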
